A study of Mus musculus with 4 samples.

How the data were processed

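The data were RNA counts per gene for 4 libraries, 2 WT and 2 Sox17eKO, each from the outflow tracts of 10 pooled hearts at embryonic day 12.5, with 20 mice per genotype per the labels' protocols. Total RNA was isolated with TRIzol and made into Illumina strand-specific libraries, per the labels' protocols. The authors deposited raw read counts per Ensembl gene, not normalized. Per the submitters' processing notes, TopHat2, HTSeq and the mm10 build were used, and the versions, the annotation release and the strand setting were not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

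The table held 45706 genes, of which 45143 matched a symbol in GENCODE M21 (GRCm38, the assembly that mm10 names) and 563 did not. Coordinates, gene classes and exonic lengths were taken from that annotation, which may differ from the release the authors counted on. The 5 HTSeq summary rows were left out of library sizes and tests. Of uniquely placed reads (genes, no feature and ambiguous together), the share outside features was 22.2% and 20.4% in WT replicates 1 and 2 and 34.1% and 29.5% in Sox17eKO replicates 1 and 2, and the ambiguous share was 5.05%, 6.22%, 3.38% and 5.39% in the same order. Alignments that were not unique made up 72.5% to 79.0% of all rows of the table, and these are alignments, not reads. Replicates differed by more than sampling noise (chi-square per degree of freedom 5.16 in WT and 6.72 in Sox17eKO), so each was counted as its own sample. Counting intervals (95%) cover counting error only, and reads without molecular identifiers are not independent molecules.

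The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, prior count 0.125) with TMM factors and genotype as the only term, on the 16570 genes that passed filterByExpr. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Log2 fold changes are those of Sox17eKO over WT from the fit, a standard error is the size of the log2 fold change divided by the square root of F, and levels are TMM-scaled CPM (counts relative to library size). The fit had 2 residual degrees of freedom before moderation, and the biological coefficient of variation was 0.0791. The 35 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated. The lists, the test design, the main alternatives and the rule for named genes were fixed before the data were examined. The rule named Sox17, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between the genotypes (leaving out predicted gene names), and up to 4 called members of each list. It also named the 3 members with the smallest p of the pan-endothelial, arterial, endocardial and smooth muscle lists and all 6 of the PDGF list. It gave 64 genes, 53 of them called.

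The scripts were tested on simulated counts for the same 16570 genes, with 200 genes changed. Of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, 10%, 54%, 76% and 96% were called, 2.48% of the calls were false, and no gene was called where none had been changed. These rates hold for counts without a trend on transcript length and with each gene's spread between pools set by its level alone. With such a trend added to the simulated Sox17eKO libraries, 128 unchanged protein-coding genes were called before the trend was removed and 3 after. A list raised 1.3-fold in the simulation was past the threshold with the preset correlation (camera adjusted p = 3.05e-15). It was not with an estimated correlation (camera adjusted p = 0.457), so at this number of pools the latter test can miss such a change. The simulated genes varied independently of each other. The simulation therefore cannot tell whether the preset correlation is adequate where members of a list vary together.

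Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, the fit without the robust option, replicate number as a block, each library left out in turn, and fry for the lists. Added after seeing the data were fits on protein-coding genes only and fits in which a smooth trend of each library on exonic length and gene span, on GC content, or on all of these was removed (mgcv 1.9.3). Removing a trend also removes any difference between the genotypes that runs with length.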

Results

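RNA was sequenced from the outflow tract, the arterial end of the embryonic heart that forms the aortic and pulmonary roots, of C57BL/6 mouse embryos at embryonic day 12.5. The series compared wild-type (WT) embryos with Sox17eKO embryos, in which the gene for the endothelial transcription factor SOX17 was deleted in the endothelium of the aortic root by a Cre recombinase under an Nfatc1 enhancer. Each library came from a pool of 10 hearts, with 2 pools per genotype. The p-values rest on the spread between pools, which the fit estimated from the gene's own 2 pools per genotype and from other genes. Reads assigned to genes numbered 12880081 and 8113463 in WT replicates 1 and 2, and 14306550 and 21883956 in Sox17eKO replicates 1 and 2. Reads placed outside annotated exons made up 21.3% ± 1.28 (SD, n = 2) of uniquely placed reads in WT and 31.8% ± 3.27 (SD, n = 2) in Sox17eKO. The purpose stated for the comparison was to find targets of SOX17.

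Sox17, the targeted gene, was lower in both Sox17eKO libraries than in both WT libraries. Its level was 6.44 ± 0.55 CPM (library-scaled counts) in WT and 2.79 ± 0.044 in Sox17eKO (mean ± SD, n = 2 pools each). The fitted level in Sox17eKO was 43.8% of that in WT, a log2 fold change of -1.19 with a standard error of 0.23 (edgeR adjusted p = 0.00574). These levels rested on 78 and 54 reads in the WT libraries and 40 and 62 in the Sox17eKO libraries. Sox17 (ENSMUSG00000025902) lies on chromosome 1 from 4490931 to 4497354 on the minus strand of mm10, where the plus-strand gene Gm37587 overlaps it. The counts cannot tell Sox17 reads of endothelium outside the deleted territory from reads of any part of the gene left in the deleted cells. Without WT replicate 2, the shallowest library, the log2 fold change was -1.12 and its edgeR adjusted p was 0.0786.

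**Figure D1:**
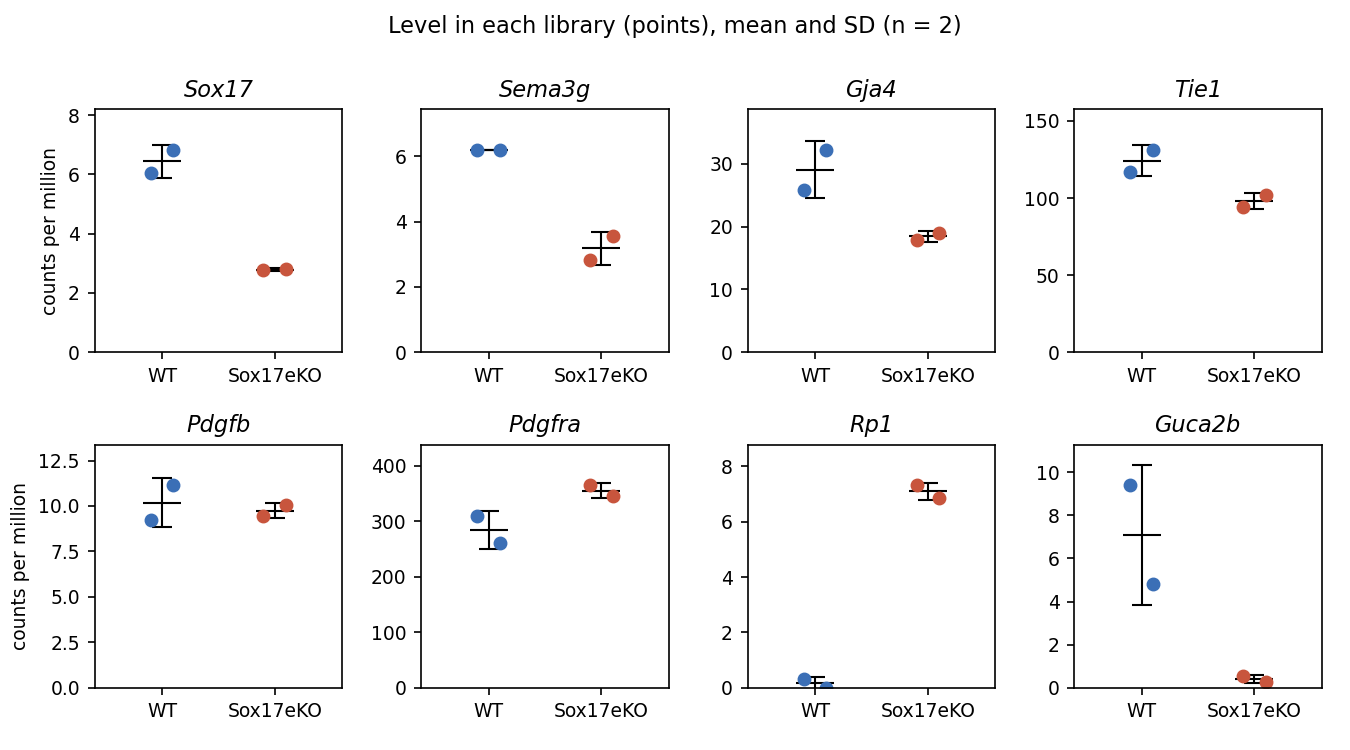
Level of 8 genes in CPM (vertical axes, each starting at 0) in the WT and Sox17eKO libraries. Points are libraries, and the horizontal bar with whiskers is the mean ± SD of 2 pools. Sox17 stood at 6.05 and 6.83 in WT against 2.76 and 2.82 in Sox17eKO, whereas the Pdgfb points of the genotypes overlapped.

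Among called genes with a mean of at least 1 CPM, Rp1, whose product is an axonemal microtubule protein of photoreceptors, rose most in Sox17eKO. It was covered by 4 and 0 reads in the WT libraries and by 106 and 151 reads in the Sox17eKO libraries, a ratio of 37.3 at equal depth (95% counting interval 14.4 to 138). Its fitted log2 fold change was 5.15 with a standard error of 0.45 (edgeR adjusted p = 6.73e-06). It was 4.47 without WT replicate 2, and without WT replicate 1 the WT group had 0 reads. Rp1 lies on chromosome 1 from 3999557 to 4409241 on the minus strand, 81689 bp beyond the 3' end of Sox17, and was named only because of its rank. Ttn, which encodes the giant sarcomere protein titin, rose from 7298 ± 1149 to 18858 ± 755 CPM (mean ± SD, n = 2), a log2 fold change of 1.37. Other genes among the 10 largest rises were noncoding or lay inside other genes. They were Phxr4 in Maml2 (1.74), Prox2os antisense to Prox2 (1.67), Hm629797 in Phkb (1.64), AU015336 within P3h2 (1.61), BC002189 in Trim55 (1.57), Mhrt antisense to Myh7 (1.497), the microRNA gene Mir322 (1.46) and the small nuclear RNA gene Rnu1b1 (1.44). Phxr4, Hm629797, AU015336 and BC002189 lie on the same strand as the gene around them. No strand setting would tell their reads from intronic reads of that gene. Prox2os and Mhrt lie on the opposite strand to Prox2 and Myh7. The strand setting of the counting was not given in the sources used here, so reads of these pairs may not have been told apart. With 1 library left out, the Phxr4 and BC002189 calls held in all 4 fits, those of Hm629797, Mhrt, Mir322 and Rnu1b1 in 1 and those of Prox2os and AU015336 in 0, and the log2 fold change ranged from 0.98 to 2.99 for Mhrt, 0.68 to 1.86 for Rnu1b1 and 1.01 to 2.37 for Prox2os.

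The largest fall among such genes was that of Guca2b, which encodes the gut peptide uroguanylin, from 7.10 ± 3.24 to 0.412 ± 0.197 CPM (mean ± SD, n = 2), with a log2 fold change of -4.22. C3, the central complement component, fell to a fitted 25.7% of its WT level (log2 fold change -1.96, edgeR adjusted p = 0.00214). Spp1, which encodes osteopontin, and Abcb1b, which encodes a drug efflux pump, fell with log2 fold changes of -1.66 and -1.48. The other genes among the 10 largest falls were Sox17, Tprn (-0.99), Sema3g (-0.94), Crlf2 (-0.74), Rtl3 (-0.66) and C1qtnf4 (-0.66). With 1 library left out, the Guca2b, C3 and Abcb1b calls held in all 4 fits, the Sox17 call in 3, the Sema3g and C1qtnf4 calls in 1 and the Tprn, Crlf2 and Rtl3 calls in 0. The Spp1 call was lost without WT replicate 1 and without Sox17eKO replicate 2. Its log2 fold change ranged from -2.09 to -1.04 with 1 library left out. With the length trend removed the Tprn, Crlf2, Rtl3 and C1qtnf4 calls ended, although most of each fall remained (log2 fold changes -0.90, -0.59, -0.57 and -0.49).

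Of 16570 genes tested, 886 changed between the genotypes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 684 of them higher and 202 lower in Sox17eKO. Changes were mostly modest, since 153 genes were at least 2-fold higher and 7 at least 2-fold lower. With scaling by library size only, 769 genes were higher and 111 lower. The counts depended on single libraries, with 103 genes called without WT replicate 2 and 289 without Sox17eKO replicate 1. Of the 53 called genes named here, 11 stayed past the threshold without WT replicate 2, 24 without Sox17eKO replicate 1, 23 without Sox17eKO replicate 2 and 36 without WT replicate 1, and 9 in all of these fits (Rp1, Ttn, Ryr2, Guca2b, C3, Abcb1b, Xist, Phxr4 and BC002189). With a smooth trend on transcript length removed from each library, an alternative chosen after seeing the data, 177 protein-coding genes were called, against 749 in a fit on the same protein-coding genes without that step. They held 119 of the 616 protein-coding genes called in the main fit.

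Of 20 arterial endothelial genes, Sox17, Gja4 and Sema3g fell and none rose, the same count adjusted over the list alone. Gja4, the gap junction protein connexin 37, fell from 29.1 ± 4.49 to 18.5 ± 0.847 CPM (log2 fold change -0.64 with a standard error of 0.12, edgeR adjusted p = 0.00551). Sema3g, a secreted class 3 semaphorin, fell from 6.20 ± 0.0041 to 3.19 ± 0.509 CPM (log2 fold change -0.94 with a standard error of 0.23, edgeR adjusted p = 0.0229). Of 22 pan-endothelial genes, Tie1, an endothelial receptor tyrosine kinase, fell with a log2 fold change of -0.34 (edgeR adjusted p = 0.0204) and 21 did not pass, also adjusted over the list alone. Eng and Ramp2 had log2 fold changes of -0.20 and -0.19 that did not pass. No endocardial gene of 12 passed over all genes, and 2 fell adjusted over the list alone. Klf2, a flow-responsive factor, had a log2 fold change of -0.48 (edgeR adjusted p = 0.061), Cytl1 one of -0.69 (edgeR adjusted p = 0.0859) and Plvap one of -0.19 (edgeR adjusted p = 0.287). None of 9 venous and lymphatic endothelial genes passed. Relative to other genes, the pan-endothelial and arterial lists were lower (camera adjusted p = 0.0164 and 0.0472), and both had an adjusted p = 0.84 with an estimated correlation. Neither passed with a GC trend removed (0.0614 and 0.0872), without WT replicate 2 or without Sox17eKO replicate 1. The arterial list also did not pass without WT replicate 1, with limma-voom (0.138), with library size scaling (0.0517) or with a filter at a mean of 1 CPM (0.0592). In fits chosen after seeing the data, both lists passed with the length trend removed (0.0194 and 0.00153) and with the length and GC trends removed (0.0341 and 0.00344). With an estimated correlation neither list passed in those fits. The arterial list held Sox17, the deleted gene, in every one of these tests, and no fit left it out. Of the 20 arterial genes, 8 had a higher fitted level in Sox17eKO in the main fit. Without WT replicate 2 none of Gja4, Sema3g and Tie1 passed (edgeR adjusted p = 0.103, 0.128 and 0.235). Without Sox17eKO replicate 1 neither Sema3g nor Tie1 did (0.135 and 0.173), and without WT replicate 1 Sema3g did not (0.0847).

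In the PDGF pathway list of 6 genes, Pdgfra, a receptor of mesenchymal cells, rose with a log2 fold change of 0.32 (edgeR adjusted p = 0.0401) and the other genes did not pass. Pdgfb, an endothelial ligand for mural cells, was at 10.2 ± 1.35 CPM in WT and 9.75 ± 0.428 in Sox17eKO (mean ± SD, n = 2). Its log2 fold change of -0.04 had a 95% interval of -0.37 to 0.29. The values were 0.04 for Pdgfa, 0.09 for Pdgfc, 0.07 for Pdgfd and -0.05 for Pdgfrb, none past the threshold. Of 20 smooth muscle genes, Myocd, a coactivator of the smooth muscle program, rose (0.31) and Cnn1, the actin-binding protein calponin, fell (-0.35). Tagln had a log2 fold change of -0.24 that did not pass (edgeR adjusted p = 0.106). The list was not past the threshold as a whole (camera adjusted p = 0.436). The Myocd call ended without WT replicate 1 (edgeR adjusted p = 0.211), and the Pdgfra, Myocd and Cnn1 calls ended without WT replicate 2, without either Sox17eKO replicate and with the length trend removed (after that step log2 fold changes of 0.20, 0.25 and -0.25 and edgeR adjusted p = 0.199, 0.171 and 0.0898).

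Of 22 genes of valve mesenchyme and endocardial transformation, Vcan and Fbn2 rose and Dcn fell. Adjusted over the list alone, 4 rose and 2 fell. Vcan, the proteoglycan versican of the cardiac jelly, rose from 1671 ± 304 to 2398 ± 130 CPM (log2 fold change 0.52), and Fbn2, fibrillin-2, had a log2 fold change of 0.38. Dcn, the proteoglycan decorin, fell (-0.32). In the extracellular matrix list of 22 genes Vcan and Fbn2 also rose, and Loxl1, an enzyme that crosslinks elastic fibers, fell (-0.44, edgeR adjusted p = 0.00962). In the axon guidance list of 21 genes the receptor Robo1 rose (0.43) and Sema3g fell, with 5 rising and 2 falling adjusted over the list alone. In the cartilage list of 9 genes the transcription factors Sox5 (0.46) and Sox6 (0.33) rose. Znrf3, a negative regulator of Wnt receptors, was the 1 gene of 21 in the Wnt list that rose (0.53), and Bmp10, a cardiac ligand, the 1 of 22 in the TGF-beta and BMP list (0.53). None of 18 Notch pathway genes passed, and Tie1 was the 1 of 20 in the VEGF, angiopoietin and chemokine list. With the length trend removed, Loxl1, Dcn, Bmp10 and Sema3g stayed past the threshold, whereas Vcan (0.31), Fbn2 (0.15), Robo1 (0.10), Sox5 (0.14), Sox6 (0.03) and Znrf3 (0.40) did not. The axon guidance and extracellular matrix lists, not past the threshold in the main fit, were then lower (both camera adjusted p = 0.0247; adjusted p = 0.790 and 0.900 with an estimated correlation), and did not pass with the length and GC trends removed (0.0628 and 0.113). Each gene called in this paragraph lost its call without WT replicate 2 and without at least 1 other library.

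Of 20 cardiomyocyte genes, Ttn, Ryr2 and Myom1 rose and none fell, with 4 rising and 2 falling adjusted over the list alone. Ryr2, the calcium release channel of the sarcoplasmic reticulum, rose from 385 ± 29.8 to 645 ± 26.1 CPM (log2 fold change 0.74), and Myom1, a sarcomeric M-band protein, had a log2 fold change of 0.36. The list median was -0.04 while its mean was 0.08, and the list was not past the threshold (camera adjusted p = 0.292). Nppa, the atrial natriuretic peptide gene, fell (-0.34, edgeR adjusted p = 0.0158) and was the 1 called gene of 10 in each of the ventricular and atrial lists. None of 9 outflow tract myocardium genes or 10 second heart field genes passed. Acta1, skeletal alpha-actin, which the embryonic heart also expresses, fell as the 1 of 8 skeletal muscle genes (-0.31). Of 12 epicardial genes, Upk3b (-0.35) and Lrrn4 (-0.53), both mesothelial markers, fell, and the list was lower (camera adjusted p = 0.00292; adjusted p = 0.84 with an estimated correlation). After removal of the length trend the log2 fold change was 0.68 for Ttn and 0.31 for Ryr2, both past the threshold, as was Lrrn4 (-0.47). Nppa (-0.16), Myom1 (0.20), Acta1 (-0.16) and Upk3b (-0.28) were not. Without WT replicate 2, and without Sox17eKO replicate 2, none of Myom1, Nppa, Acta1, Upk3b, Lrrn4 and the epicardial list (camera adjusted p = 0.0621 and 0.165) passed, and the Myom1, Nppa and Acta1 calls also ended without Sox17eKO replicate 1 and the Acta1 call without WT replicate 1.

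The megakaryocyte and platelet list and the erythroid list had the lowest medians. All 17 erythroid genes had a lower fitted level in Sox17eKO, with a median log2 fold change of -0.52 (camera adjusted p = 2.95e-08; adjusted p = 0.84 with an estimated correlation). The embryonic globin gene Hbb-y was the 1 that fell by itself (-0.56, edgeR adjusted p = 0.0288), and reads shared between globin genes leave its level uncertain. The 8 megakaryocyte and platelet genes were also all lower in fitted level, with a median of -0.64 (camera adjusted p = 0.00198; adjusted p = 0.84 with an estimated correlation). The list did not pass without WT replicate 1 (0.0780). Itga2b, the platelet integrin subunit, fell (-0.59). None of 16 macrophage and leukocyte, 9 neural crest and Schwann precursor, 10 neuronal, 5 lung and foregut or 10 liver genes passed. The Hbb-y call ended without WT replicate 1, without WT replicate 2 or without Sox17eKO replicate 1 (edgeR adjusted p = 0.0632, 0.290 and 0.168) and with the length trend removed (log2 fold change -0.36, 0.321), and the Itga2b call without either WT replicate or Sox17eKO replicate 2 (0.126, 0.0955 and 0.165).

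Of 22 cell cycle genes, Cenpf, a kinetochore protein, rose (0.37) while the list as a whole was lower (camera adjusted p = 0.0472; adjusted p = 0.84 with an estimated correlation). Of 75 ribosomal protein genes, Rps27l fell (-0.42), and the list was lower (camera adjusted p = 0.00366; adjusted p = 0.84 with an estimated correlation). Of 60 replication-dependent histone genes, 5 fell, among them Hist2h3b (-0.55), Hist1h2ai (-0.41) and Hist1h3d (-0.35), and Hist1h2ak rose (0.40). The histone list was lower (camera adjusted p = 5.32e-05; adjusted p = 0.84 with an estimated correlation), and near-identical copies leave single histone genes uncertain. Of 23 mitochondrially encoded genes mt-Nd4 (0.46), mt-Cytb (0.44), mt-Nd6 (0.41) and mt-Nd5 (0.35) rose, and the list did not pass (camera adjusted p = 0.602). Tested among protein-coding genes only, which left 8 of the 23 members, the list was higher (camera adjusted p = 1.74e-06, and 8.19e-16 with the length trend removed), alternatives chosen after seeing the data. It had an adjusted p = 0.772 and 0.790 with an estimated correlation in these fits, and the list of 23 turned to lower without Sox17eKO replicate 1 (0.873). Xist, the RNA that silences an X chromosome, rose (0.75, edgeR adjusted p = 8.53e-05). As a noncoding gene it was not in the fits on protein-coding genes, so its call was not tested with the length trend removed. The 4 other genes of the X and Y list did not pass (Ddx3y -0.32, Uty -0.21, Kdm5d 0.05 and Eif2s3y -0.41). No gene of the hypoxia and glycolysis list (18 genes) or the immediate early and heat shock list (15 genes) passed. With the length trend removed, the cell cycle, ribosomal and histone lists were not past the threshold (camera adjusted p = 0.159, 0.306 and 0.749). The ribosomal and histone lists were then in the higher direction. The calls of Cenpf (0.16), Rps27l (-0.23), Hist1h2ai (-0.21) and Hist1h3d (-0.20) ended. Those of mt-Cytb (0.59), mt-Nd5 (0.48) and mt-Nd6 (0.59) also ended, although their log2 fold changes were then larger. Hist2h3b (-0.36), Hist1h2ak (0.60) and mt-Nd4 (0.61) kept their calls. Without WT replicate 2 the cell cycle, ribosomal and histone lists did not pass (0.102, 0.0882 and 0.699), nor did the cell cycle list without WT replicate 1 (0.0780) or Sox17eKO replicate 1 (0.390) or the ribosomal list without Sox17eKO replicate 2 (0.108). The Xist call held without any 1 library, the Hist1h2ak call ended without WT replicate 1 (edgeR adjusted p = 0.0802), and the other called genes named in this paragraph lost theirs without WT replicate 2, all but Hist2h3b and mt-Nd4 also without at least 1 other library.

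**Figure D2:**
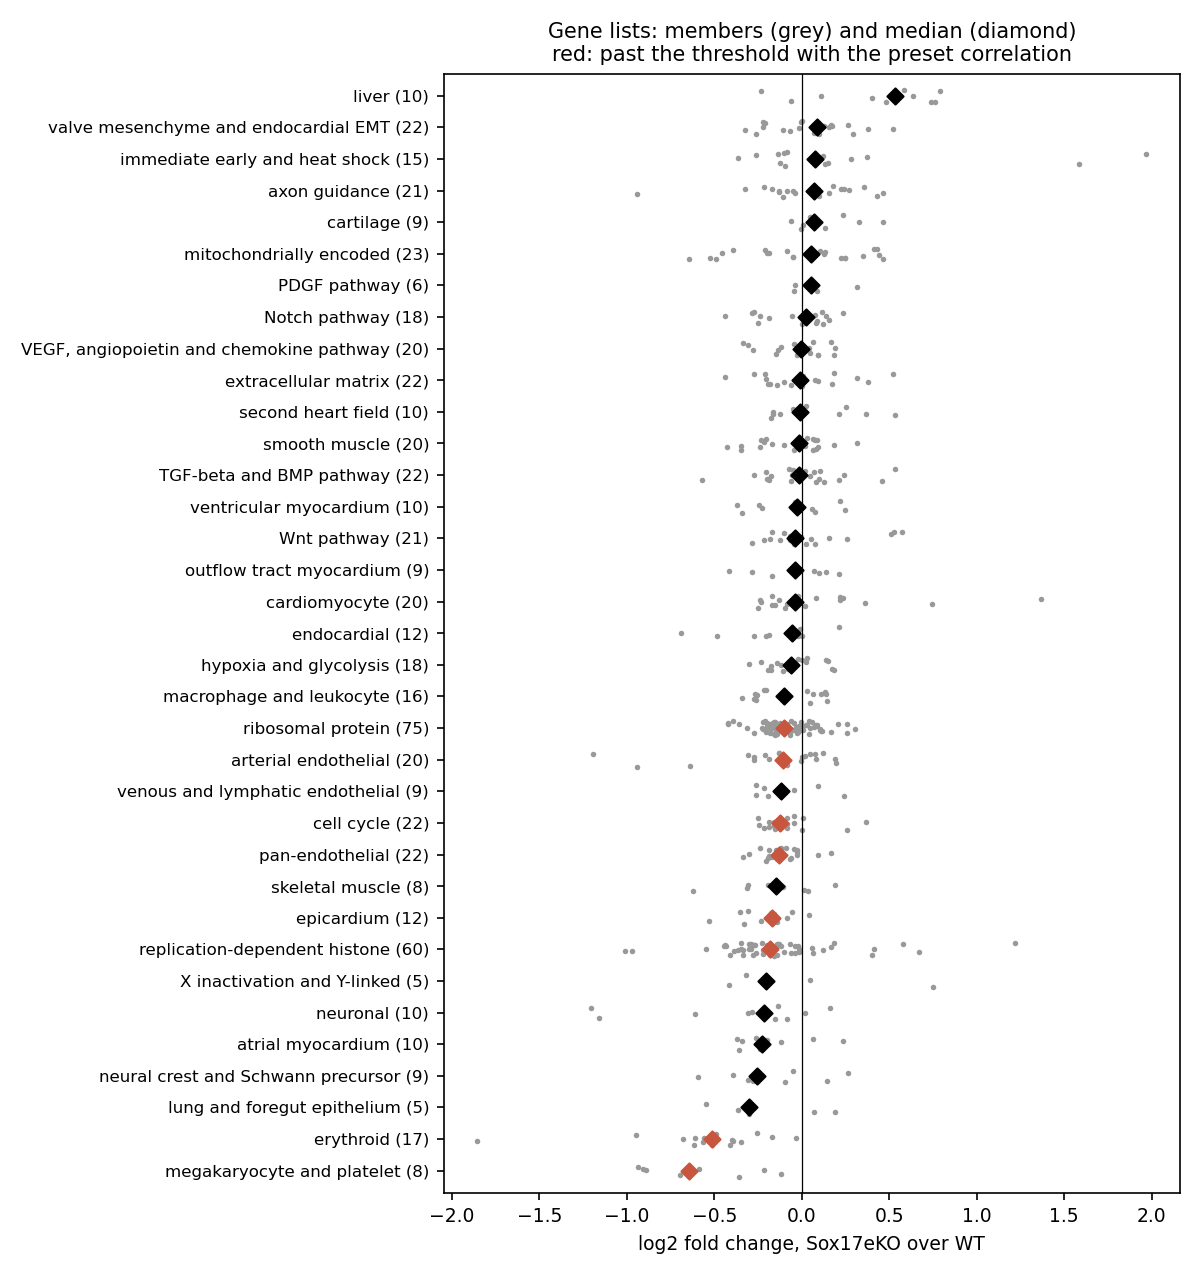
Log2 fold change of Sox17eKO over WT (horizontal axis) for the tested members of 35 gene lists, with the number of tested members in parentheses. Grey points are genes and diamonds are list medians, in red where camera with the preset correlation passed. The megakaryocyte and platelet (-0.64) and erythroid (-0.52) medians lie lowest.

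Genes with long transcripts and genes inside introns were higher in Sox17eKO. Among protein-coding genes, the median log2 fold change went from -0.16 in the shortest of 10 equal groups by exonic length to 0.21 in the longest, which held 317 of the 482 protein-coding genes that rose. The median exonic length was 12.4 kb for those that rose, 2.52 kb for the 134 that fell and 4.58 kb for all tested. Of 557 genes of the annotation class TEC, models that await experimental evidence, 126 rose and none fell (median 0.83). Of 104 sense intronic genes 20 rose and none fell (median 0.93). Of 411 small nuclear, nucleolar and Cajal body RNA genes 42 fell and 1 rose (median -0.24).

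**Figure D3:**
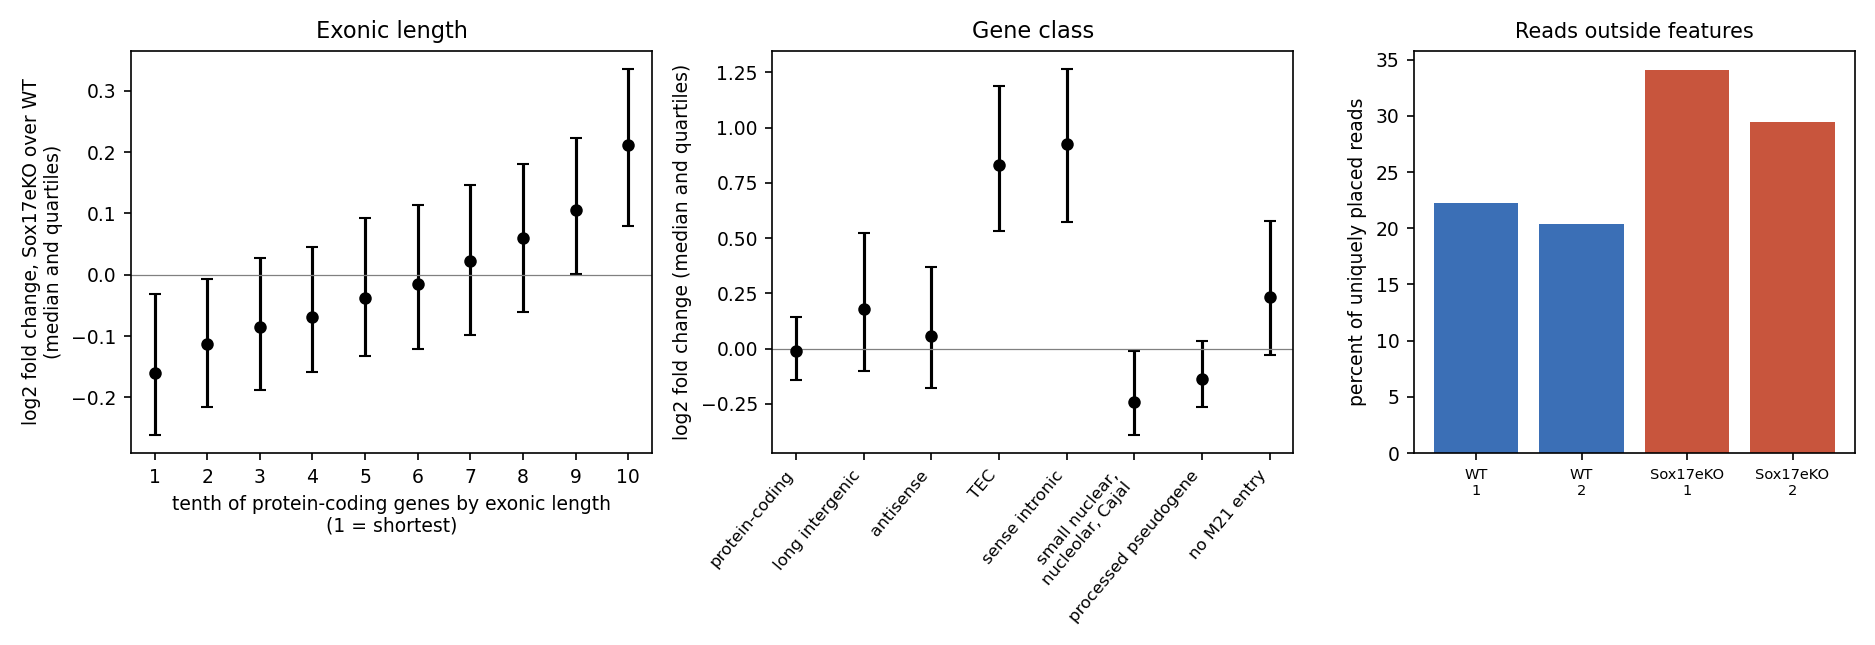
Left and middle, median log2 fold change of Sox17eKO over WT with quartiles (whiskers), by 10 groups of exonic length for protein-coding genes and by annotated gene class. Right, reads outside annotated features as a percent of uniquely placed reads, a bar per library, with 22.2 and 20.4 in WT and 34.1 and 29.5 in Sox17eKO.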

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

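All tests in this part were chosen after the results they bear on had been seen. Reads outside annotated features, which enter no comparison, made up 31.8% of uniquely placed reads in Sox17eKO on average, above the level in both WT control libraries.

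This excess went with the rise of long and intronic transcripts. Genomic DNA as its source is argued against by olfactory receptor and other silent gene families, whose counts per Mb reached at most 6.68% (upper 95% limit) of the rate that DNA would need. More unspliced RNA is consistent with the rise of TEC and sense intronic genes, whose median log2 fold change was 0.85. As the whole cause of the length trend, unspliced RNA was tested on 363 intronless genes, where it alone would give no trend. The median log2 fold change of the 121 longest was above that of the 121 shortest by 0.072 (95% interval 0.011 to 0.15, permutation p = 0.0073, 2-sided). Genes are not independent replicates, which limits this test. The same difference was 0.22 for genes with introns. The rule written for this test also weighed the 0.072 against the 0.22, and by that rule the test could not tell. Each set was cut by its own lengths, so the 0.072 and the 0.22 may span different lengths. How much of the length trend in genes with introns comes from unspliced RNA stays open. With 2 libraries per genotype, a difference in RNA handling and an effect of genotype cannot be told apart for this trend.

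Rp1 rose more than any other named gene. The length trend is argued against as its cause, since the log2 fold change was 4.91 with that trend removed, and photoreceptor cells are argued against by 13 markers that together had 62 counts in Sox17eKO against 257 of Rp1. The other 13 tested genes within 1 Mb of Sox17 had a median log2 fold change of -0.10 (range -0.27 to 1.09). None was called and none rose like Rp1, which argues against a rise of that size across the region. Gm19938, beyond Rp1 on the same strand, was at 1.06 with a standard error of 0.46, so a smaller change there stays open. Transcription that reaches Rp1 from the altered Sox17 allele, 81689 bp away on the same strand, remains a possible explanation that gene counts, which hold no junctions, cannot decide.

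Sox17, Gja4 and Sema3g fell. The median of the pan-endothelial list was -0.13 (95% interval -0.18 to -0.06). That of the whole arterial list was -0.11 (95% interval -0.24 to 0.03). Both intervals came from resampling the genes of the list, which are not independent replicates, and hold no spread between pools. Each gene's value plus 2 standard errors lay below both intervals. For Gja4 and Sema3g this cannot decide on a lower share of endothelial cells, since both were picked as called falls. Nor can it decide on a lower share of arterial cells, since the 3 genes were picked as the called falls of the arterial list. Sox17 was named in advance, and its log2 fold change was -1.19 with a standard error of 0.23. For Sox17 this argues against a lower share of endothelial cells as the whole cause. The length trend is argued against by a median of -0.91 for the 3 genes with the trend removed, where all 3 stayed past the threshold. A response of Gja4 and Sema3g to loss of SOX17 is a hypothesis that these data suggest and that was found and tested on the same libraries, and neither gene passed without WT replicate 2 (edgeR adjusted p = 0.103 and 0.128).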

How the results depend on the processing

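The length and GC fits were chosen after seeing the data. Of 53 called named genes, 9 (Rp1, Ttn, Ryr2, Guca2b, C3, Abcb1b, Xist, Phxr4 and BC002189) stayed past the threshold in every setting that gave them an adjusted p, and no called gene of the 886 changed sign under a planned setting. Xist, Phxr4 and BC002189, not annotated as protein-coding, were in none of the fits on protein-coding genes. Of 616 protein-coding calls, 18 changed sign with the length trend removed, 17 with length and GC and 0 with GC. Where no cause is given, the cause was not tested.

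Calls numbered 424 with DESeq2 (294 higher, 130 lower), where 392 of the 886 genes got no adjusted p because its filter left them out, 517 with limma-voom (421 and 96), and 1364 with no filter on low counts (387 lower), where more genes were tested. Scaling by library size left 111 lower genes and the fit without the robust option 105. Without 1 library the calls ranged from 103 to 970, the higher genes from 90 to 641 and the lower genes from 13 to 329. Among protein-coding genes only 749 were called, with the length trend removed 177 (98 and 79), with the length and GC trends 296 (144 higher), and with the GC trend 489 were lower. Replicate number as a block gave 1684 calls (1107 and 577). The numbers are not stated to pair the pools, and the deviations of replicates did not run together (correlation -0.03).

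Sox17 had no adjusted p in DESeq2 (log2 fold change -1.20, unadjusted p = 0.00103), and its log2 fold change without 1 library ranged from -1.29 to -1.12. Of the named genes, 22 were kept by DESeq2 (26 had no adjusted p), 34 by limma-voom, and 11 to 36 without 1 library. Of the 44 tested in the trend fits, which left out the 9 not annotated as protein-coding, 19 were kept with the length trend removed and 24 with length and GC. Lists past the threshold numbered 8, but 0 with an estimated correlation, 0 by fry and 2 to 9 without 1 library. With the length trend, and with length and GC, removed, the ribosomal list (adjusted p = 0.306 and 0.607) and the histone list (0.749 and 0.625) turned to higher, not past the threshold. The cell cycle list was also lost (0.159 and 0.0625), as with library size scaling (0.0787) and a mean of at least 1 CPM (0.0624), and axon guidance turned to lower (0.0247 and 0.0628). With the length trend removed 6 lists passed that had not in the main fit. They were axon guidance, venous and lymphatic endothelial (0.0289), endocardial (0.0221) and extracellular matrix (0.0247), all lower, and immediate early and heat shock (0.0289) and mitochondrially encoded (8.19e-16), both higher. With length and GC they were 5, namely venous and lymphatic endothelial (0.0498), endocardial (0.0341), cardiomyocyte (0.0341, higher), immediate early and heat shock (0.0341) and mitochondrially encoded (1.26e-16). With GC the pan-endothelial and arterial lists were lost (0.0614 and 0.0872), cardiomyocyte (0.0424) and mitochondrially encoded (2.68e-05) were higher, and extracellular matrix turned to higher (0.624). None of the lists that passed in these fits or among protein-coding genes did so there with an estimated correlation (lowest adjusted p = 0.772). The arterial list was lost with limma-voom (0.138), library size scaling (0.0517) and a mean of at least 1 CPM (0.0592). With all libraries and the preset correlation, no list besides it and the cell cycle list was lost under a planned setting.

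Other lists turned sign. The liver list was higher without Sox17eKO replicate 1 (7.07e-08), lower without Sox17eKO replicate 2 (1.20e-06), and not past the threshold without WT replicate 2 (0.157), with limma-voom (0.983), library size scaling (0.941) or the replicate block (0.843), all lower. Without 1 library the adjusted p ranged from 0.0317 to 0.722 for hypoxia and glycolysis (0.912 with length and GC), 0.00259 to 0.873 for skeletal muscle, 0.000471 to 0.873 for immediate early and heat shock, 0.359 to 0.873 for mitochondrially encoded and 0.131 to 0.873 for extracellular matrix.

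The 5 PDGF genes other than Pdgfra, none past the threshold, changed sign. Pdgfb was 0.0597 with the GC trend removed and 0.0440 with length and GC. Without 1 library the ranges were -0.0107 to 0.0831 for Pdgfa, -0.185 to 0.0803 for Pdgfb, -0.108 to 0.386 for Pdgfc, -0.0076 to 0.154 for Pdgfd and -0.174 to 0.0631 for Pdgfrb. At this depth and number of pools, 10% of genes with the smallest simulated change were called.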

Other observations

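The tests and genes in this part were chosen after their values had been seen. Genes of the gamma protocadherin cluster, cell adhesion molecules made from variable first exons, were higher in Sox17eKO, where 15 of 22 tested rose and none fell (median log2 fold change 0.76). With the length trend removed, 12 of 21 rose (median 0.64). None of 16 beta protocadherin genes passed (median 0.18). The gamma genes share their last exons, so their counts depend on how shared reads were assigned. Removing the length trend does not remove reads of unspliced RNA, and their part in this rise was not tested.

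Of 248 long intergenic RNA genes 18 rose and 2 fell (median 0.18). Among noncoding RNAs picked by name, the log2 fold change was 0.81 for Malat1, 0.79 for Neat1, 0.95 for the imprinted antisense RNA Kcnq1ot1, 0.80 for Airn and 0.52 for Meg3 (edgeR adjusted p = 0.00019, 0.000182, 9.14e-05, 4.09e-05 and 0.00179). These RNAs were not in the fits on protein-coding genes, so their calls were not tested with the length trend removed. Liver and yolk sac transcripts differed between libraries without following genotype. Afp was at 60.7 and 8.73 CPM in WT replicates 1 and 2 and at 3.38 and 107.6 in Sox17eKO replicates 1 and 2, and Apob at 31.1, 4.43, 1.72 and 59.6 in the same order.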
